A study of Mus musculus with 30 samples.

How the data were processed

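Total RNA from heart and white adipose tissue was purified with a miRNeasy kit and made into libraries with the Nugen Universal Plus mRNA kit, then sequenced on a NovaSeq, per the labels' protocols. The values are estimated counts per gene, which the authors made with kallisto 0.46 against GRCm38.p6, per the submitters' processing notes. They were deposited without scaling to library size. How transcripts were summed to genes, the annotation release and any strand setting are not given in the sources used here, so overlapping and antisense genes, and members of gene families, cannot be told apart with certainty. Pseudoalignment divides reads shared between similar transcripts by estimation, and 30.8% of the values were not whole. The table held 36558 Ensembl gene IDs, of which 35856 were given a symbol and coordinates from the GENCODE mouse annotation of GRCm38, 702 were not, and 76 IDs shared a symbol with another.

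The labels name 30 libraries, with 7 per group in heart and 8 per group in adipose tissue. The table held 29 of them, and the GFP heart library L10 was not analysed here. Groups were taken from the sample titles. No pair of libraries in a group was identical, and the lowest chi-square per degree of freedom between the counts of a pair was 3.66 in heart and 8.52 in adipose tissue, so no library was counted as a repeat of another. Totals of 15.95 to 33.02 (in units of 1e6) per library limit the precision of genes with few counts. Intervals and the limit of 3 counts that a count of 0 allows cover counting error only.

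Estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. In each tissue, genes were kept by filterByExpr with the vector as the group, libraries were scaled by TMM, and the quasi-likelihood test with robust estimation of the spread compared F11 with GFP, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Unless another tool is named, adjusted p-values of genes come from this test, and fold changes are F11 over GFP. The difference between tissues was tested as an interaction contrast in a fit over all libraries. CPM values are counts per 1e6 TMM-scaled counts of the library over all genes. For F11, which did not pass the filter in heart, a two-sided exact permutation test of the difference of mean CPM was used. The square root of the common dispersion was 0.105 in heart, 0.355 in adipose tissue and 0.309 over both.

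Lists of genes for pathways and cell types, 44 in all with 759 of 762 entries found, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes where at least 5 members were tested, which held for 39 lists in heart and 40 in adipose tissue. At an adjusted p under 0.05 over the lists, 10 passed in heart and 15 in adipose tissue. With an estimated correlation only the pair of clock lists in heart passed and none in adipose tissue. The self-contained test fry, which asks whether the genes of a list move one way on balance, passed both clock lists, the sarcomere list and glycolysis in heart and none in adipose tissue (lowest adjusted p 0.373). The genes named in the text followed a rule. It takes F11, the 10 genes with the largest positive and the 10 with the largest negative fold change among those past the threshold with an ordinary symbol, a mean of at least 1 CPM in 1 group, and at least 6 of 7 (heart) or 7 of 8 (adipose) F11 libraries on the side of the fold change. Where too few passed, it takes the lowest p-values up to 10 genes, given as values. It adds up to 4 called members, or else the 2 members with the lowest p, of each list that passed or held a called gene, the 6 lowest p-values of the tissue difference, and 5 BMP and SMAD genes. One gene that the rule takes is not reported here. Clock genes named for the tissue difference, and single genes named as markers of other tissues, were chosen after their values were seen.

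Alternatives were other size factors, no filter and a stricter filter of a mean of 1 CPM, DESeq2 1.42.0, limma voom with sample quality weights on the unrounded values, a threshold of 0.1, a fit over all libraries, a surrogate variable from sva 3.50.0, and leaving out each library in turn. The groups, tests, lists, naming rule and these alternatives were fixed before the data were examined. Covariates for a clock, an atrial and a macrophage score, fits without libraries rich in transcripts of other tissues, and a permutation test of log2(CPM + 1) for F11 were added after seeing the data. The gene counts of both tissues and of the tissue difference, and the correlation between tissues, were compared with 99 other seeded splits of the libraries, 100 with the real one.

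The fits were tested on simulated data with 50 genes changed at each fold. In heart 40, 68, 88 and 98% of genes changed 1.25, 1.5, 2 and 4-fold were recovered over 14651 genes, with 7 false calls among 154. In adipose tissue the shares were 22, 46, 70 and 88% over 15180 genes, with 4 false calls among 117. For the tissue difference they were 8, 38, 66 and 80% over 16447 genes, with 6 false calls among 102. Both lists raised 1.2-fold were called in both tissues, and of 40 lists 1 unchanged list was called in heart and 0 in adipose tissue by camera at the preset correlation. The simulated genes varied independently of each other. For the tissue difference each simulated gene also had the same mean level in both tissues, apart from the added change, unlike the real libraries. In the real lists the estimated correlation between genes ran from 0.00821 to 0.994 in heart and from −0.136 to 0.988 in adipose tissue. The false calls and recovered shares therefore need not hold for genes that vary together. Those of the tissue difference need not hold for genes whose level differs between heart and adipose tissue. Figures were drawn with matplotlib 3.10.9.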

Results

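RNA was sequenced from the heart and the white adipose tissue of male C57BL/6J mice that carried an adeno-associated virus vector, AAV8, encoding either F11 or green fluorescent protein (GFP). AAV8 mainly transduces hepatocytes, and F11 encodes coagulation factor XI, a plasma protease precursor made by the liver. The mice ate a high-fat diet with l-NAME, an inhibitor of nitric oxide synthase, for 7 weeks and were 15 weeks old when the tissues were taken. This diet is used as a mouse model of heart failure with preserved ejection fraction. Heart was represented by 6 GFP and 7 F11 libraries and adipose tissue by 8 GFP and 8 F11 libraries. The total estimated count per library, in units of 1e6, was 25.75 to 30.6 in GFP hearts and 28.1 to 33.02 in F11 hearts. In adipose tissue it was 15.95 to 22.5 with GFP and 16.8 to 26.3 with F11. Transcripts of the mitochondrial genome took 33.6 ± 1.13% (SD, n = 6) of counts in GFP hearts and 33.2 ± 0.721% (SD, n = 7) in F11 hearts. The corresponding shares in adipose tissue were 5.62 ± 2.29% (SD, n = 8) and 5.14 ± 0.917% (SD, n = 8). The labels give each library its own number without stating that each came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

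The gene carried by the vector was examined first, as a check of the labels. F11 lies on chromosome 8 at 45241174 to 45262031 (GRCm38, ENSMUSG00000031645). In heart it was close to the counting limit, with 3 counts summed over the F11 libraries and 13 over the GFP libraries, each sum coming from 2 libraries. The ratio of F11 to GFP, corrected for library size, was 0.191, with an exact 95% interval of 0.0349 to 0.695 that covers counting error only. The mean level was 0.014 ± 0.0251 CPM (SD, n = 7) against 0.0688 ± 0.14 CPM (SD, n = 6), and a two-sided exact permutation test over all 1716 splits gave p = 0.437. A count of 0 allowed up to 0.0909 to 0.117 CPM, depending on the library. Of the 13 GFP counts, 11 came from library L2, which also held 116.1 CPM of Alb, the albumin transcript of hepatocytes. In adipose tissue F11 averaged 1.11 ± 1.62 CPM (SD, n = 8) with GFP and 6.55 ± 4.74 CPM (SD, n = 8) with the F11 vector. All 8 F11 libraries lay above the GFP median of 0.475 CPM. L147, at 0.514 CPM, barely did so and lay below GFP libraries L135, L136, L137 and L139. F11 thus gave no check of the label of L147 or of the heart labels. A two-sided exact permutation test of the mean CPM gave p = 0.00295 over 12870 splits. The edgeR fit estimated a log2 fold change of 2.56 (SE 0.82), which failed the adjustment over all genes (unadjusted p = 0.00668, adjusted p = 0.9996). Alb ranged from 34.3 to 3380 CPM in GFP and from 7.45 to 3205 CPM in F11 adipose libraries. How reads of a vector transcript were assigned to mouse F11, and to its paralog Klkb1, is uncertain under estimated counts.

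In heart, the comparison of F11 with GFP addresses which transcripts differ with the F11 vector. Neither factor XI protein nor liver F11 was measured here. Genes of the circadian clock were among those with the largest changes. Arntl, which encodes the clock activator BMAL1, fell from 11.3 ± 1.64 CPM (SD, n = 6) to 3.53 ± 0.976 CPM (SD, n = 7), and its partner Npas2 fell from 5.19 ± 1.26 to 2.5 ± 0.595 CPM. The repressor Per2 rose from 8.09 ± 1.9 to 20.2 ± 3.51 CPM, Ciart from 2.8 ± 0.706 to 7.32 ± 0.904 CPM, and the clock output factor Dbp from 43.1 ± 6.83 to 82.7 ± 10.9 CPM. For each of these genes, all 7 F11 libraries lay on the same side of the GFP median. In all, 14684 genes were tested, of which 76 were higher and 52 lower with F11 at an adjusted p under 0.05. The median absolute log2 fold change of these 128 genes was 0.40, and 9 of them differed more than 2-fold.

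**Figure D1:**
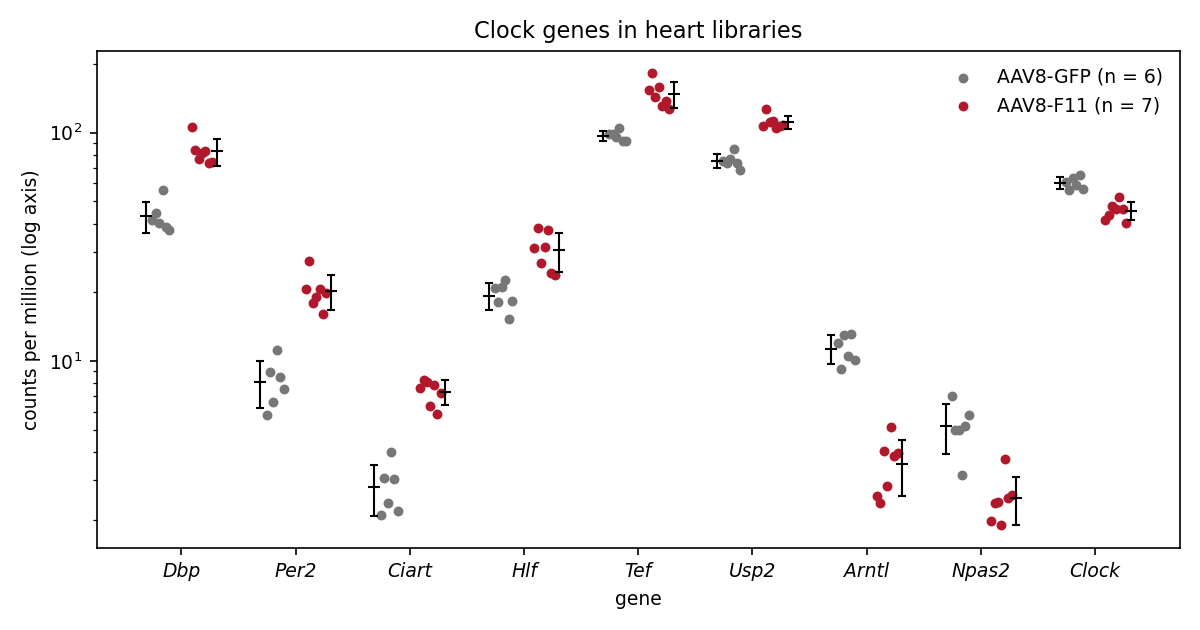
CPM (counts scaled to library size) on a log axis for 9 clock genes in the 6 GFP (grey) and 7 F11 (red) heart libraries, with black marks for the mean and bars for 1 SD. Dbp, Per2, Ciart, Hlf, Tef and Usp2 were higher and Arntl, Npas2 and Clock lower in the F11 libraries.

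All 12 measured clock genes driven by CLOCK and BMAL1 had a positive fold change (median log2 0.58). Of these, 8 rose over all genes tested and 12 of 12 adjusted over the list alone. Usp2 had a log2 fold change of 0.56 (SE 0.05, adjusted p = 6.96e-05), Ciart of 1.39 (SE 0.13, adjusted p = 7.04e-05), Tef of 0.61 (SE 0.07, adjusted p = 0.000346) and Dbp of 0.94 (SE 0.10, adjusted p = 0.000397). Of the 5 genes of the opposite phase, 3 fell, namely Arntl (log2 −1.68, SE 0.16, adjusted p = 0.000139), Clock (−0.40, SE 0.06, adjusted p = 0.00167) and Npas2 (−1.05, SE 0.17, adjusted p = 0.00577). Adjusted over the list alone, 3 fell and 1 rose. Both clock lists passed camera (adjusted p = 7.08e-54 and 5.09e-13). They also passed with an estimated correlation (adjusted p = 0.000563 and 0.000737).

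Among the genes taken by the naming rule and outside the clock lists, the largest rises were those of Hif3a, a hypoxia-inducible factor subunit (log2 1.59, SE 0.20, adjusted p = 0.000396), and of Zbtb16, a zinc finger transcription factor (log2 1.42, SE 0.24, adjusted p = 0.0161). Zbtb16 went from 47.3 ± 7.32 CPM (SD, n = 6) to 126.9 ± 42.8 CPM (SD, n = 7). Hhipl1, Hecw2, Agap2 and Rhobtb1 rose by log2 0.92, 0.74, 0.73 and 0.72. Hlf, a clock output factor that belongs to the clock list driven by CLOCK and BMAL1, rose by 0.66. Spon2, a secreted matrix protein, fell from 3.11 ± 0.696 to 0.96 ± 0.458 CPM (log2 −1.69, SE 0.26, adjusted p = 0.00401). Fam124b, Cdo1 and Adam19 fell by 1.36, 0.92 and 0.70 on the log2 scale, and Arhgap28, Sox4, Slc41a3 and Vgll3 by 0.70, 0.68, 0.68 and 0.67. All of these genes had 7 of 7 F11 libraries on the side of the fold change. The call of Hlf, Cdo1 or Adam19 was lost when single libraries were left out, with an adjusted p of up to 0.0691, 0.0621 and 0.0562 without GFP library L2, L5 and L5.

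**Figure D2:**
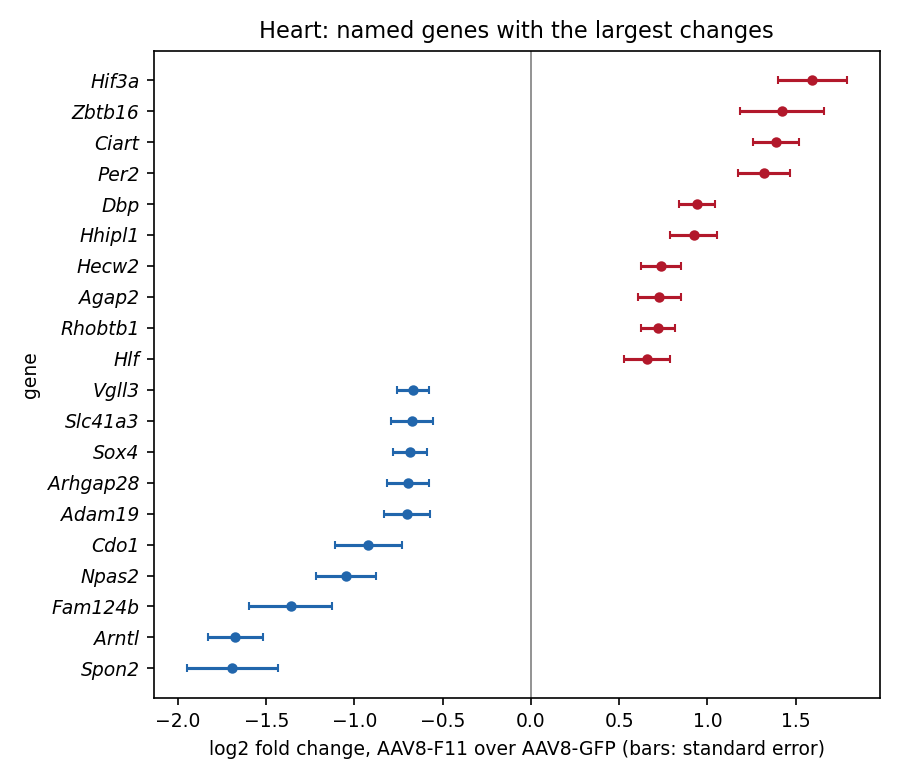
Log2 fold changes of F11 over GFP in heart for the 10 genes that rose and the 10 that fell most under the rule for named genes, which leaves out genes under a mean of 1 CPM in both groups, with bars of 1 standard error. Values run from −1.69 for Spon2 to 1.59 for Hif3a.

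Contractile genes of the cardiomyocyte had small positive fold changes in all 18 members measured (median log2 0.14). Myh6, the main adult myosin heavy chain, rose by a log2 of 0.30 (SE 0.04, adjusted p = 0.00192), and Tcap, a Z-disc protein, rose from 450.4 ± 42.5 CPM (SD, n = 6) to 616 ± 70.7 CPM (SD, n = 7). These were the 2 members past the threshold over all genes, and 9 rose adjusted over the list alone. The list passed camera (adjusted p = 3.93e-11), with adjusted p = 0.0544 with an estimated correlation. Among fetal and stress genes 9 of 12 had a positive fold change and none passed singly by edgeR over all genes, while 1, Myh7, was higher adjusted over the list alone. Myh7, the slow myosin heavy chain, had a log2 fold change of 0.78 (SE 0.21, adjusted p = 0.119, and 0.0309 with DESeq2) and Nmrk2 of 0.40 (adjusted p = 0.192). That list passed camera with adjusted p = 0.0144 (adjusted p = 0.779 with an estimated correlation). Without GFP library L8, which held 0.383 CPM of the atrial transcript Myl7 and 705.9 CPM of the globin transcript Hba-a1, its call was lost (adjusted p = 0.115). All 7 atrial markers had a negative fold change (median log2 −0.37), a list that did not pass camera (adjusted p = 0.843) but passed without L8 (mean log2 −0.64, adjusted p = 0.0474).

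Of 16 glycolytic genes measured in heart 14 had a positive fold change, and Hk1, a hexokinase, rose (log2 0.25, SE 0.05, adjusted p = 0.0114). Adjusted over the list alone, 6 rose. The list passed camera (adjusted p = 0.000193), with adjusted p = 0.405 with an estimated correlation. Irs1, an adaptor of the insulin receptor, fell from 30.2 ± 2.66 CPM (SD, n = 6) to 20.3 ± 2.03 CPM (SD, n = 7), a log2 change of −0.57 (SE 0.07, adjusted p = 0.000346). It was 1 of 14 insulin signalling genes to pass over all genes, and 3 rose and 3 fell adjusted over the list alone. Dgat2, which makes triglyceride, rose by a log2 of 0.27 (adjusted p = 0.026). Flt1, a VEGF receptor, rose by 0.32 (adjusted p = 0.0171). Mmp14, a membrane metalloproteinase, fell by 0.27 on the log2 scale (adjusted p = 0.0274) as the 1 called member of 27 matrix genes, whose list did not pass camera (adjusted p = 0.38) but passed without L5 (adjusted p = 0.0231) or L35 (0.0391). The calls of Dgat2 and Mmp14 were lost when single libraries were left out, with adjusted p of up to 0.0797 without L5 and 0.0744 without L1.

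Zbtb16 was also the 1 of 10 glucocorticoid receptor targets past the threshold in heart. Adjusted over that list alone, 4 rose and 1 fell, and 6 of 10 had a positive fold change (camera adjusted p = 0.00617, and adjusted p = 0.813 with an estimated correlation). The call of this list was lost without GFP library L9 (adjusted p = 0.066) or F11 library L38 (adjusted p = 0.0584). BMP signalling was examined because a cardiac effect of factor XI has been studied through it. No BMP gene passed singly by edgeR. Bmp7 had a log2 fold change of 0.14 (adjusted p = 0.75), Smad1 of −0.10 (0.407), Smad5 of −0.10 (0.333), Id1 of 0.28 (0.495) and Id3 of 0.19 (0.365). Of 23 ligands, receptors, SMADs and antagonists, 5 had a positive fold change (median log2 −0.10). The lowest p-values were those of Fst (log2 −0.74, adjusted p = 0.164) and Bmp2 (−0.44, adjusted p = 0.294). That list passed camera downward (adjusted p = 0.0135), with adjusted p = 0.405 with an estimated correlation, and its call was lost without F11 library L40 (adjusted p = 0.0581). The 12 targets of BMP and SMAD signalling had 6 positive fold changes (camera adjusted p = 0.985).

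Lists of mesothelial markers, macrophage markers and interferon-stimulated genes passed camera in heart and were lost with an estimated correlation. All 12 mesothelial markers had a negative fold change (median log2 −1.11), including Nkain4 (log2 −1.28, adjusted p = 0.166) and Krt19 (−1.44, adjusted p = 0.189). Both of these were at low levels. Nkain4 averaged 0.5727 ± 0.2705 CPM (SD, n = 6) with GFP and 0.2325 ± 0.1281 CPM (SD, n = 7) with F11. Krt19 averaged 0.742 ± 0.374 and 0.271 ± 0.24 CPM. The list passed camera (adjusted p = 4.56e-06), with adjusted p = 0.405 with an estimated correlation, and 2 members fell adjusted over the list alone. Of 19 macrophage markers 4 had a positive fold change (median log2 −0.09), with Ptprc at −0.29 (adjusted p = 0.117) and Lyz2 at −0.22 (adjusted p = 0.151). The list passed camera (adjusted p = 0.00575), with adjusted p = 0.813 with an estimated correlation, and its call was lost without L2 (adjusted p = 0.0931), L9 (0.066) or L40 (0.0899). Interferon-stimulated genes had 26 of 29 positive fold changes (median log2 0.17), with Ifit3b at 0.34 (adjusted p = 0.417) and Oas1a at 0.31 (adjusted p = 0.443), both members of gene families whose reads can be shared. This list passed camera (adjusted p = 0.00512), with adjusted p = 0.988 with an estimated correlation, and its call was lost without L5 (adjusted p = 0.12) or L31 (0.328).

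Several adipocyte transcripts that were at low levels in heart had negative fold changes there. Adipoq, the adiponectin gene, averaged 1.26 ± 0.882 CPM (SD, n = 6) with GFP and 0.344 ± 0.272 CPM (SD, n = 7) with F11 (log2 −1.85, adjusted p = 0.206). Ucp1 averaged 2.08 ± 2.65 and 0.0466 ± 0.0949 CPM, with 6.27 CPM in GFP library L1 and 4.47 CPM in L5. Of 15 white adipocyte markers 6 had a positive fold change (median log2 −0.07, mean −0.51), and 1 rose and 4 fell adjusted over the list alone. The list did not pass camera (adjusted p = 0.38), but passed without GFP library L8 (adjusted p = 0.0104). Cdo1 and Vgll3, which fell in heart, were far higher in adipose tissue, at 814.4 ± 283.1 and 125 ± 36.5 CPM (SD, n = 8) with GFP against 3.23 ± 0.995 and 5.98 ± 0.743 CPM (SD, n = 6) in GFP hearts. Adipoq averaged 2046 CPM in GFP adipose tissue. GFP hearts thus held a larger share of the adipose level of Cdo1 and Vgll3 than of Adipoq. Adipoq overlapped between the groups, with 0.0348 and 0.714 CPM in GFP hearts L8 and L6 against 0.906 CPM in F11 heart L38. Cdo1 and Vgll3 did not overlap. Their lowest GFP hearts held 2.215 and 4.79 CPM and their highest F11 hearts 2.111 and 4.467 CPM. These values argue against fat, as marked by Adipoq, as the whole cause of the falls of Cdo1 and Vgll3. Whether fat in the heart samples accounts for the other falls, or for a part of these, was not tested. Among the 10 named genes that fell most, Spon2 and Arhgap28 also averaged higher in GFP adipose tissue than in GFP hearts. Fam124b, Npas2, Adam19, Sox4, Slc41a3 and Arntl averaged lower. Adipoq, Ucp1 and these adipose levels were singled out after their values were seen.

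The heart counts were lower in a fit over all 29 libraries of both tissues, where the spread was shared (13 higher and 17 lower, 24 of them among the 128). In that fit Dbp had an adjusted p of 0.162, Hif3a of 0.196, Npas2 of 0.242, Irs1 of 0.634 and Usp2 of 0.939, while Arntl, Per2, Ciart, Clock, Zbtb16 and Spon2 passed. The counts were higher with DESeq2 (226 and 151) and limma voom (122 and 79). Library numbers run in blocks by group, so an order of collection or preparation that followed these numbers would coincide with the vector. Whether the order did so is not known here.

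In adipose tissue no gene passed the edgeR test after adjustment among 15229 tested, with 638 at an unadjusted p under 0.05 (389 higher and 249 lower with F11) and a lowest adjusted p of 0.355. DESeq2 called 6 genes higher and 0 lower, limma voom called 0, and the fit over all 29 libraries called 4 higher and 0 lower. The 6 from DESeq2 were Cep250, Setd5, Ric1, Kmt2b, Gucy1b1 and Fryl, and the 4 were Cep250, Setd5, Kmt2b and Gucy1b1. Cep250, a centrosomal protein gene, averaged 66 ± 3.02 CPM (SD, n = 8) with GFP and 78.9 ± 4.5 CPM (SD, n = 8) with F11 (log2 0.26, SE 0.04), with 8 of 8 F11 libraries above the GFP median. The histone methyltransferase gene Kmt2b had a log2 fold change of 0.17 (adjusted p = 0.523), Setd5 of 0.22 (0.446), Ric1 of 0.20 (0.463) and Fryl of 0.24 (0.852). Gucy1b1 and Gucy1a1, the subunits of the nitric oxide receptor soluble guanylate cyclase, had log2 fold changes of 0.44 (SE 0.10, adjusted p = 0.852) and 0.43 (SE 0.10, adjusted p = 0.939). Gucy1b1 averaged 17 ± 3.01 CPM (SD, n = 8) and 23.1 ± 2.18 CPM (SD, n = 8). Arhgef17 and Apbb2 had log2 fold changes of 0.35 and 0.25 (adjusted p = 0.939 each).

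Markers of mural cells, the pericytes and smooth muscle of vessels, had 9 of 12 positive fold changes in adipose tissue (median log2 0.24). Kcnj8, a potassium channel of pericytes, averaged 20 ± 3.71 CPM (SD, n = 8) with GFP and 30.1 ± 6.51 CPM (SD, n = 8) with F11 (log2 0.59, SE 0.15, adjusted p = 0.939), and Notch3 had a log2 fold change of 0.32 (adjusted p = 0.939). The list passed camera (adjusted p = 4.11e-06), with adjusted p = 0.176 with an estimated correlation, and both genes were higher adjusted over the list alone. Endothelial markers had 16 of 17 positive fold changes (median log2 0.13), with Tek at 0.14 and Cdh5 at 0.21 (adjusted p = 0.9996 each). Their list passed camera (adjusted p = 0.000595), with adjusted p = 0.672 with an estimated correlation. All 19 macrophage markers had a negative fold change (median log2 −0.20), among them Cd163 at −0.15 and C1qa at −0.20 (camera adjusted p = 0.00422, and adjusted p = 0.726 with an estimated correlation). The macrophage call was lost without L133 (adjusted p = 0.242), L142 (0.221), L145 (0.107) or L146 (0.109), and the endothelial call without L141 (0.0504).

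Cardiac transcripts were unevenly spread over the adipose libraries. GFP library L140 held 4126 CPM of Myh6 against a GFP median of 17, and GFP library L138 held 82.8 CPM, while the highest F11 library, L147, held 29.1 CPM. All 16 sarcomere genes measured had a negative fold change (median log2 −4.60), with Myl2 at −4.93 and Myh6 at −4.90 (adjusted p = 0.939 each). The list passed camera (adjusted p = 2.33e-07), with adjusted p = 0.669 with an estimated correlation, and 14 members were lower adjusted over the list alone. Without L140 and the F11 library L142, which held 6003 CPM of the epididymal transcript Gpx5, the mean log2 fold change went from −3.91 to −0.34 (adjusted p = 0.0148). Cardiac stress genes (median log2 −0.64, adjusted p = 0.0025, with Nppa at −4.66 and Xirp2 at −4.87) and calcium and ion channel genes (−0.28, adjusted p = 0.00279, with Pln at −4.04 and Ryr2 at −2.76) passed camera the same way. With an estimated correlation their adjusted p was 0.208 and 0.672, and without both libraries 0.0634 and 0.36. The mitochondrial transcript share of L140 was 11.1%.

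Genes of energy metabolism had mostly negative fold changes in adipose tissue, beside the cardiac transcripts of L140. Of 29 fatty acid oxidation genes 2 were positive (median log2 −0.18, camera adjusted p = 1.77e-10, and adjusted p = 0.376 with an estimated correlation). Fabp3 had a log2 fold change of −4.73 and Angptl4 of −0.27, and without L140 and L142 the list's mean went from −0.39 to −0.08 (adjusted p = 0.0205). None of 41 nuclear genes of oxidative phosphorylation had a positive fold change (median log2 −0.14), with Ndufb3 at −0.13 and Cycs at −0.20, none past the edgeR threshold. Camera gave adjusted p = 1.74e-08, and adjusted p = 0.672 with an estimated correlation. Without L140 and L142 the mean of that list turned from −0.14 to 0.00487 (adjusted p = 0.95), and without L140 alone it was −0.0144 (adjusted p = 0.352). Of 16 glycolytic genes 2 were positive (median log2 −0.14), with Pfkl at −0.24 and Eno3 at −1.53, or 0.08 without L140 (camera adjusted p = 6.72e-06, and adjusted p = 0.208 with an estimated correlation). Without L140 and L142 the mean went from −0.24 to −0.08, and the list still passed.

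**Figure D3:**
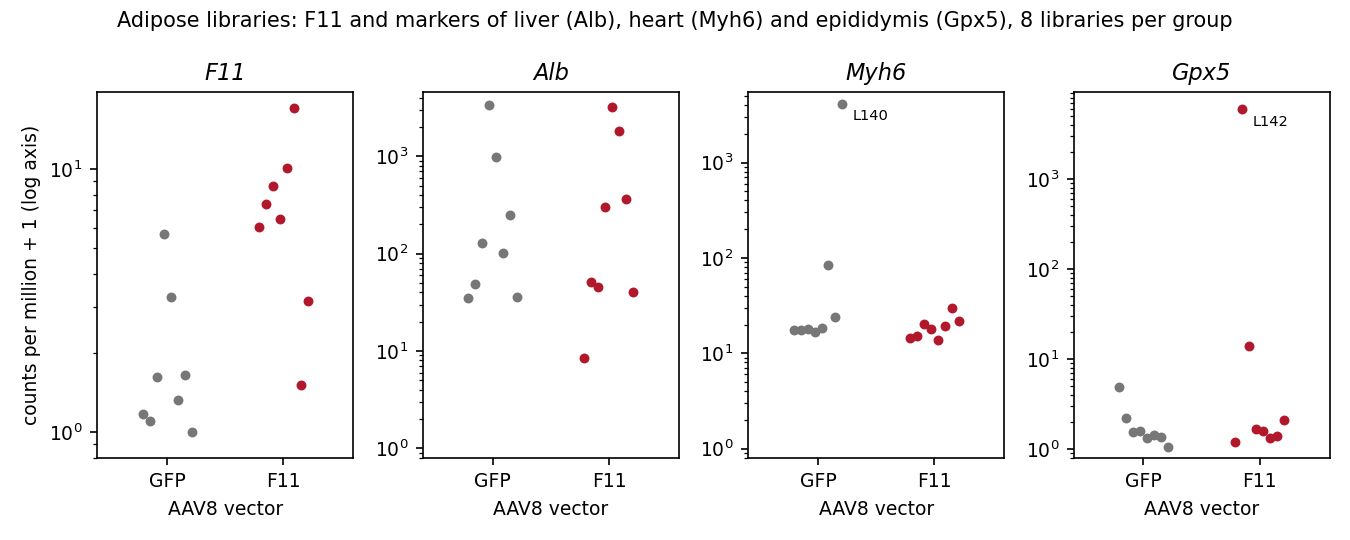
CPM plus 1 on log axes for F11, Alb, Myh6 and Gpx5 in the 8 GFP (grey) and 8 F11 (red) adipose libraries, each point being 1 library. Myh6 reached 4126 CPM in L140 and Gpx5 reached 6003 CPM in L142.

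Stress, immune and clock lists in adipose tissue passed camera and were lost with an estimated correlation. Interferon-stimulated genes had 25 of 29 positive fold changes (median log2 0.14, adjusted p = 0.000187, and adjusted p = 0.672 with an estimated correlation), with Cmpk2 at 0.23 and Ifit2 at 0.27. Inflammatory cytokine genes had 6 of 23 positive (median −0.14, adjusted p = 0.00621, and adjusted p = 0.672 with an estimated correlation). Among them Socs3 had a log2 fold change of −0.49 (adjusted p = 0.939) and Il1a of −0.82 (adjusted p = 0.9996). Antigen presentation genes had 2 of 17 positive (median −0.08, adjusted p = 0.029, and adjusted p = 0.726 with an estimated correlation), with H2-K1 at −0.18 and Psmb10 at −0.11. Heat shock genes had 3 of 12 positive (median −0.10, adjusted p = 0.00422, and adjusted p = 0.176 with an estimated correlation), with Hsp90aa1 at −0.16 and Hspa8 at −0.20. Of the clock genes driven by CLOCK and BMAL1, 11 of 12 had a positive fold change (median 0.21, adjusted p = 0.00291, and adjusted p = 0.672 with an estimated correlation), with Per1 at 0.47 and Per3 at 0.37. The opposite phase had 1 of 5 positive (median −0.23, adjusted p = 0.0469, and adjusted p = 0.669 with an estimated correlation), with Nfil3 at −0.56 and Npas2 at −0.37. The interferon call was lost without L145 (adjusted p = 0.0826), and the call of the list driven by CLOCK and BMAL1 without L133 (0.0552). The inflammatory call was lost without L133 (0.0941), L134 (0.102), L142 (0.0717) or L146 (0.0656). The antigen presentation call was lost without L133, L134, L137, L139, L142 or L146 (adjusted p of up to 0.71, without L142). That of the opposite clock phase was lost without L133, L134, L135, L138, L139, L141, L144, L145, L146 or L147 (up to 0.145, without L133).

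The BMP genes in adipose tissue had log2 fold changes of 0.59 for Bmp7, 0.15 for Smad1, 0.07 for Smad5, 0.17 for Id1 and 0.06 for Id3 (adjusted p = 0.9996 each). Bmp7 rested on F11 library L142, with 19 CPM against a group median of 1.81 CPM, and its log2 fold change was −0.67 without that library and −0.64 with DESeq2. That of Id1 was −0.02 without F11 library L145.

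**Figure D4:**
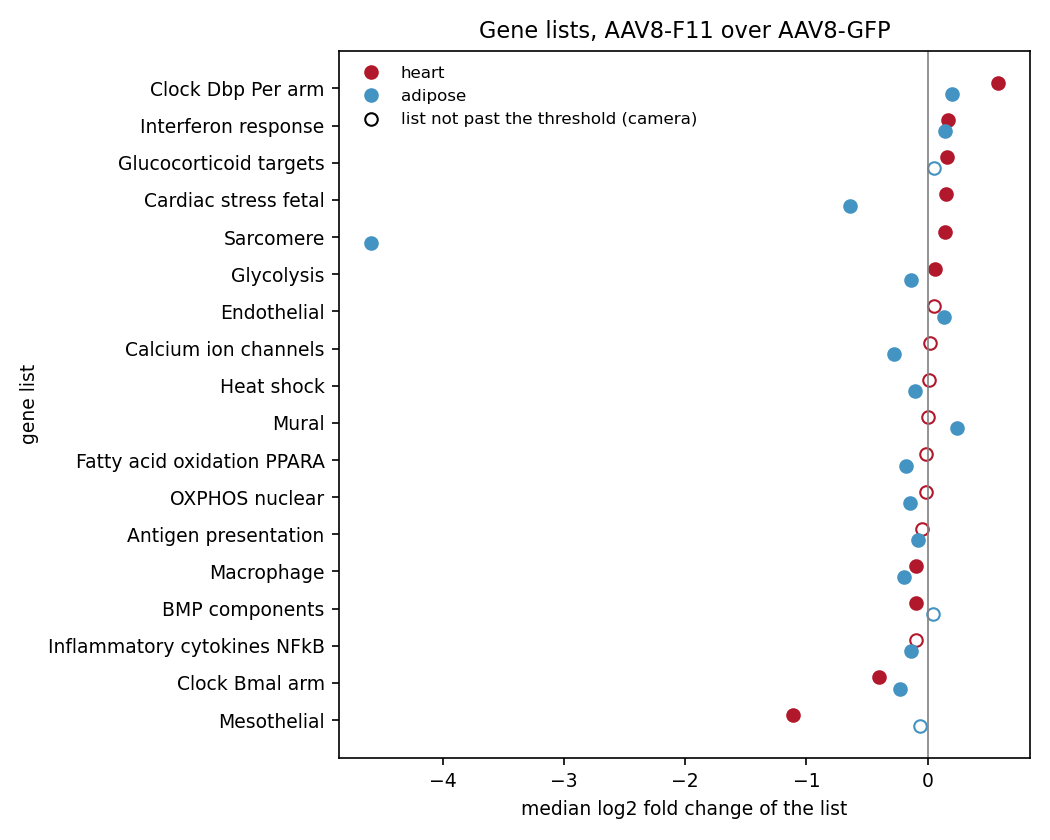
Median log2 fold change of F11 over GFP for 18 gene lists in heart (red) and adipose tissue (blue), with filled points for lists past camera at the preset correlation of 0.01. The sarcomere point of adipose tissue at −4.60 rests mainly on library L140.

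Whether the vector acted differently in the 2 tissues was tested directly. The effect of F11 differed for 4 of 16526 genes, with 1228 at an unadjusted p under 0.05, and all 4 were among the 128 heart calls. Ypel2 had a log2 fold change of −0.56 in heart and 0.08 in adipose tissue, a difference of −0.64 (SE 0.08, adjusted p = 0.000607). For Zfp395 the values were −0.43 and 0.17 (difference −0.60, SE 0.11, adjusted p = 0.0424), for Midn 0.46 and −0.09 (0.56, SE 0.10, adjusted p = 0.0424), and for Mn1 0.43 and −0.06 (0.50, SE 0.09, adjusted p = 0.0431). Rbm7 (difference −0.29, adjusted p = 0.113) and Fam13c (−0.70, adjusted p = 0.118) did not pass. The clock genes did not pass either, with a difference of −1.44 for Arntl (SE 0.36, adjusted p = 0.213), 1.22 for Per2 (SE 0.31, adjusted p = 0.23) and 0.72 for Dbp (SE 0.33, adjusted p = 0.629). This fit shares its spread over both tissues, with a square root of the common dispersion of 0.309 against 0.105 in heart alone. In it the heart change of Dbp itself did not pass, while those of Arntl and Per2 did. These p-values therefore do not show that the clock shift was alike in the 2 tissues. Of the 128 heart calls 124 were tested in adipose tissue and 60 had the same sign there, 4 with the same sign and 4 with the opposite sign at an unadjusted p under 0.05. Across 13825 genes, which are not independent replicates, the fold changes of the 2 tissues had a Pearson correlation of −0.0447 and a Spearman correlation of −0.0245. The correlation was 0.00566 without L140 and L142, and DESeq2 and limma voom called 172 and 24 genes in the test of the difference. The 4 genes fell to 1 or 2 on leaving out any single library except L2, L31, L136, L142 and L148, and Ypel2 passed each time.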

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

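The clock scores of heart and adipose tissue, the atrial covariate, and the tests of adipose F11 transcripts and of library L140 were chosen only after the result was seen.

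In 28 of 184 groups of 6 to 8 libraries, 1 library lay far from the others relative to the range of its group (Dixon's criterion), 11 times in heart and 17 times in adipose tissue. Chance flags about 1 in 20 groups. In F11 hearts these were Dbp at 105.8 CPM in L31, Rhobtb1 at 226.2 CPM and Usp2 at 127.4 CPM in L33, Npas2 at 3.72 CPM in L38, Myh7 at 752.1 CPM in L35 and Smad5 at 36.6 CPM in L40. In GFP hearts they were Fst at 1.79 CPM and Myh6 at 25560 CPM in L1, Nkain4 at 0.0696 CPM in L8, and Bmp7 at 1.67 CPM and F11 at 0.351 CPM in L2. GFP adipose libraries gave Ric1 at 62.4 CPM in L139 and Il1a at 1.82 CPM in L136. The other 10 in that group were in L140, with Psmb10 at 20.3 CPM, Nppa at 138.1 CPM, Xirp2 at 127.6 CPM, Myl2 at 859.8 CPM, Myh6 at 4126 CPM, Pln at 645.1 CPM, Ryr2 at 251.8 CPM, Fabp3 at 448 CPM, Cycs at 162.2 CPM and Eno3 at 122.8 CPM. F11 adipose libraries gave Kmt2b at 80.5 CPM in L144 and Myl2 at 6.27 CPM in L147. In L142 they gave Psmb10 at 21.9 CPM, Angptl4 at 407.8 CPM and Bmp7 at 19 CPM.

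The effect of F11 differed between heart and adipose tissue for Ypel2 (log2 difference −0.64), Zfp395 (−0.60), Midn (0.56) and Mn1 (0.50), by the interaction test.

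In heart, 11 clock genes shifted together, and a clock score per library (mean centred log2 CPM of the list driven by CLOCK and BMAL1 minus that of the opposite phase) was 1.27 higher with F11, which restates the shift of those genes and is no further evidence for it. A difference in sequencing depth is argued against, since 11 of the 11 genes stayed past the threshold after all heart libraries were thinned to the smallest total. The share of atrial tissue as the whole cause is argued against too, since 98.3% of their median absolute log2 fold change remained with an atrial score as a covariate. Time of day at collection may be the source and cannot be told apart from the vector, because no label gives it and the adipose clock score, 0.44 higher with F11 (SD 0.771 with GFP and 0.623 with F11), gave an exact permutation p of 0.23. An effect of the F11 vector on the clock is the biological explanation the design names, and it stays open as a hypothesis.

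F11 transcripts in F11 adipose libraries might come from the vector in fat, from liver RNA carried over, or from reads of the paralog Klkb1. Klkb1 reads counted as F11 at the rate of the GFP libraries are argued against, since the log2 ratio of F11 to Klkb1 counts was 2.78 higher in the 8 F11 libraries (SD 1.48) than in the 8 GFP libraries (SD 0.74), with a two-sided exact permutation p of 0.0014. Of the 8 F11 libraries 7 lay above the highest GFP ratio, all but L147, for which this does not hold. L145 and L146 exceeded 500 CPM of Alb and held 2.85 and 8.94 F11 counts per 1000 Alb counts. Such GFP libraries, L136 and L137, held 1.39 and 2.34. The highest F11 ratio, in L146, was 3.83 times the highest GFP ratio. That lies within a limit of 10 times for liver RNA, which was set after the data were seen. So wide a limit cannot separate liver RNA from the vector in fat, so both stay open in L145 and L146. Expected F11 counts in the other 6 F11 libraries were taken from Alb at the highest ratio of any library over 500 CPM of Alb. Observed counts were a median of 10.2 times those expected, from 0.157 times in L147 to 75.8 times in L141. With 5 of 6 above expectation, a two-sided exact sign test gave p = 0.219, and it could pass only if all 6 agreed. L141, L142, L143 and L148 held 103, 122, 130 and 38 counts against 1.4, 8.5, 6.7 and 6.2 expected. Liver RNA at that ratio is argued against as the source of most F11 counts in those libraries. In L144 (108 against 53.1) and L147 (10 against 63.7) liver RNA stays open. Whether carried-over liver RNA had a higher ratio in any of these libraries was not tested. Transcription of the vector in adipose tissue stays open as a hypothesis.

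Cardiac transcripts in the GFP adipose library L140 could come from heart RNA or from skeletal muscle. Over genes far higher in heart than in the other adipose libraries, the excess in L140 followed the heart level with a rank correlation of 0.952 across genes, at a median of 14.6% of that level, so heart RNA in the sample fits the values. Skeletal muscle is argued against, since its markers that heart lacks reached 0.0587% of the summed level of cardiac markers. Whether tissue or libraries were mixed was not tested, and no biological explanation was tested.

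Other splits of the libraries bear on whether chance can be excluded. In heart 1 of 100 splits, the real one, gave 128 genes, and the highest of the others gave 1. Chance is thus excluded at a share of 0.05, with 100 of the 1716 possible splits drawn and if the libraries were exchangeable. An order of collection or preparation that followed the vector is not addressed by this comparison. In adipose tissue the real split gave 0 by edgeR (638 at an unadjusted p under 0.05, 6 by DESeq2, 0 by limma voom) and the highest other 4953; all 100 splits reach a count of 0 by construction, so this comparison says nothing of chance. A split that calls so many genes points to a structure of the adipose samples that the vector does not follow. For the tissue difference 3 of 100 regroupings gave as many as the real 4, so chance is excluded at a share of 0.05 for a count of 4 only. That count fell to 1 or 2 on leaving out any single library except L2, L31, L136, L142 and L148, so the exclusion is not firm. The highest other gave 1882, which points to the same structure. For the correlation between tissues 38 of 100 regroupings were as far from 0 as the real −0.0447, with 0.0975 the highest other, so chance is not excluded.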

How the results depend on the processing

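The clock, atrial and macrophage scores, the fits without libraries rich in transcripts of other tissues and the permutation of log2(CPM + 1) were chosen after seeing the data. No paired analysis was possible because the library numbers are unique to each group and do not tie heart and adipose libraries to a mouse. Where no reason is given, the cause was not tested. The heart counts of 76 higher and 52 lower became 226 and 151 with DESeq2, 122 and 79 with limma voom, 13 and 17 in the fit over all libraries, whose shared spread was larger, and 171 and 1.4e+02 (rounded) at an adjusted p under 0.1, a looser threshold. Leaving out single libraries gave 51 to 119 higher (119 without L40) and 36 to 64 lower. Of the 128 calls 128 were among the 377 of DESeq2, 127 among the 201 of voom and 105 among the 150 without L8 and L40, but 24 among the 30 of the fit over all libraries and 84 among the 87 without L5. Without a filter on low counts 117 of the 128 stayed past the threshold, and 2 named heart genes lost their call. In the fit over all libraries the named genes Hif3a, Dbp, Hecw2, Agap2, Hlf, Fam124b, Npas2, Cdo1, Adam19, Vgll3, Mmp14, Myh6, Tcap, Hk1, Irs1, Dgat2, Usp2, Tef and Flt1 did not pass (adjusted p of 0.0621 to 1). All 128 kept their sign in every setting that tested them except the clock score. With the clock score as a covariate 0 and 0 passed by edgeR (413 at an unadjusted p under 0.05). That score is built from the outcome's own genes, and 90.1% of its variance lies between the groups. The median absolute log2 fold change of the 117 calls outside the clock lists went from 0.37 to 0.29, while their median SE rose from 0.07 to 0.22. With so little of the score's variance within groups, that rise was built in. The fit therefore cannot separate lost precision from a shared clock effect. For the 11 clock calls the median absolute log2 fold change went from 0.66 to 0.14 (SE 0.12 to 0.26), and 6 kept their sign. With that score 117 of the 128 calls kept their sign, and among named genes and lists signs reversed for Dbp (−0.00329), Hlf (−0.0531), Npas2 (0.38), Mmp14 (0.0349) and the interferon list (−0.18). Of 39 heart lists 10 passed, 2 with an estimated correlation, 4 with fry and 8 to 15 without single libraries. In adipose tissue the 0 higher and 0 lower by edgeR (638 at an unadjusted p under 0.05) became 6 higher with DESeq2 and 4 in the fit over all libraries, and stayed 0 without any single library and without L140 and L142. The 15 lists became 0 with an estimated correlation, 0 with fry and 12 to 22 without single libraries. Adipose lists reversed in mean log2 fold change for oxidative phosphorylation (0.00487 without L140 and L142, 0.0284 also without the 4 libraries rich in Alb) and, with the macrophage score, for cell cycle (0.0889), lipid-associated macrophage (0.13) and hepatocyte genes (−0.76). Hepatocyte genes also reversed with 1 surrogate variable (−0.36) and ran from −1.07 without L145 to 1.76 without L136, and B and plasma cell genes from −0.59 without L145 to 0.39 without L134. The 4 genes of the tissue difference became 2 without a filter, 172 with DESeq2, 24 with voom and 1 to 6 without single libraries; each left-out library except L2, L31, L136, L142 and L148 left 1 or 2. Ypel2 passed in every one of these. The correlation between tissues was 0.00304 without a filter, 0.00566 without L140 and L142, and −0.058 to −0.00707 without single libraries. Adipose F11 passed by the exact permutation of log2(CPM + 1) (difference 1.82, p = 0.00389), and its edgeR log2 fold change was 2.23 to 3.44 without single libraries. That fold change was 3.43 without L140, L142 and the 4 libraries rich in Alb (adjusted p = 0.581). The heart F11 difference was −0.0687 to 0.00152 CPM, the last without L2. Single-library losses among named heart genes were Hlf (L1, L2, L5, L8, L9, L33, L36), Cdo1 (L1, L2, L5, L35), Adam19 (L1, L2, L5, L9, L35), Mmp14 (L1, L2, L8, L31, L33, L36, L39) and Dgat2 (L5, L6, L8, L9, L33, L35, L36). Depth limits heart F11, which had 0 counts in 5 of 7 F11 and 4 of 6 GFP libraries.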

Other observations

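The clock score was chosen after seeing the data, while its test within groups was set before the result of that test was seen. Adipose libraries varied widely within each group in genes of macrophages and adipocytes. Gpnmb, a marker of lipid-laden macrophages, ranged from 36.1 to 2362 CPM with GFP and from 163.7 to 3232 CPM with F11. Col1a1, the main fibrillar collagen, ranged from 226.3 to 1415 CPM and from 293 to 1443 CPM. Lep, the leptin gene of adipocytes, averaged 3624 ± 1265 CPM (SD, n = 8) with GFP and 3325 ± 1113 CPM (SD, n = 8) with F11, and Adipoq 2046 ± 647 and 2191 ± 701.8 CPM. The first principal component held 37.4% of the variance in adipose tissue and 22.7% in heart. Ucp1, the uncoupling protein of thermogenic adipocytes, averaged 0.178 ± 0.104 CPM (SD, n = 8) with GFP and 0.475 ± 1.1 CPM (SD, n = 8) with F11, where L144 held 3.19 CPM and the highest of the others 0.171 CPM. Thermogenic genes had 3 of 11 positive fold changes (median log2 −0.65, camera adjusted p = 0.0815), a list that passed without L134 (adjusted p = 0.0478), L137 (0.0314) or L139 (0.0423). Hepatocyte genes had 13 of 17 positive fold changes in adipose tissue (median log2 0.10, camera adjusted p = 0.928), with a mean log2 of −1.07 without F11 library L145 and 1.76 without GFP library L136.

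Insulin signalling genes in heart moved both ways. The test of change in either direction, fry's mixed test, gave an adjusted p of 3.59e-07 for the list of 14, while camera gave 0.738. The mixed test passed for 15 of 39 heart lists, so it does not single this list out. Beside the fall of Irs1, Pik3r1 had a log2 fold change of 0.56 (adjusted p = 0.0614), Tbc1d4 of −0.28 (adjusted p = 0.0694) and Slc2a4, the insulin-responsive glucose transporter, of 0.15 (adjusted p = 0.125). These 3 genes were chosen after their values were seen.

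A hypothesis was that the 117 heart calls outside the clock lists may follow the same clock phase difference. If so, their deviations within groups should correlate with the clock score in the direction of the fold change. This held for 58.97% of them, against a median of 49.6% over 10000 permutations of the score within groups (one-sided permutation p = 0.277), so the test left the hypothesis open.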
